A study of Caenorhabditis elegans with 6 samples.

How the data were processed

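RNA sequencing counts of 6 libraries were analysed, from young adult C. elegans hermaphrodites given X-rays at 0, 200 or 400 Gy, with 2 libraries per dose. Per the labels' protocols, the source was a linear accelerator, RNA was extracted with Trizol, and libraries were made with a TruSeq RNA kit, which does not mark strand. The time between irradiation and harvest is not given in the sources used here. The deposited table gives, per gene, raw read counts and RPKM values for each library. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.13 and the WBcel235 build were used. The read counter, the annotation release, the strand setting and any filter are not given in the sources used here. Each deposited RPKM value equals the count divided by the length in the table and by the library's total count. Of these lengths 91.7% are multiples of 3, so they are called coding lengths. The tests used the counts, since RPKM holds no further measurement. Genes were taken by the names in the table, and 44837 of the 45292 names were found in a table of current gene names. Positions were read from the deposited table.

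Total counts ran from 9554479 to 12315765 per library. Genes with enough counts were kept by edgeR's filterByExpr, which left 14417 genes, among them 73 of the 15365 listed 21ur RNA genes. Counts were scaled by TMM, with factors from 0.751 to 1.24. The common biological coefficient of variation was 35.1%, with 5.07 prior degrees of freedom. Between replicates, the chi-square statistic per degree of freedom was 66.9, 106 and 125 at 0, 200 and 400 Gy, so libraries of a dose differed beyond counting noise and none was a copy.

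Differences between doses were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with 1 model over all 6 libraries and 3 residual degrees of freedom, since 2 libraries per dose give little information on spread alone. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors were taken from the log2 fold change and its F statistic. Lists of genes for tissues, pathways and families, written before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and at least 3 tested members. Of these lists 46 could be tested per comparison, and of 1001 genes written in them 933 were found by name and 37 by an older name. Some lists held genes that the study named from these same samples.

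Named genes followed a rule fixed beforehand. Per comparison it took the 10 genes with the largest rise and the 10 with the largest fall past the threshold (5 and 5 for 400 Gy against 200 Gy) with a mean of at least 5 CPM and libraries that did not overlap. It also took up to 4 members of each list past the threshold, and 9 genes of prior interest whatever their p. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were taken. Not every gene the rule takes is printed, and a few with almost no counts in one dose were left out after their counts were seen. Others with low counts in a dose, such as gcy-32, are printed.

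Alternatives set beforehand were DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, no filter on low counts, a mean of at least 5 CPM, only the 4 libraries compared, the replicate number as a block, leaving out each library in turn, a threshold of 0.01 and a minimum of 1 in absolute log2 fold change. For lists they were camera with an estimated correlation, fry, the block, and members of at least 5 CPM. With an estimated correlation camera takes its p-values from the 3 residual degrees of freedom, so it had little power here. Estimates also lay far above 0.01 for some lists, such as 0.93 for major sperm proteins at 200 Gy against 0 Gy. There a lost call can come from the correlation as well. The alternatives for normalized values and for a table of the authors' own comparisons had no data to apply to. Chosen after the data were examined were a length correction, which removed from each library a loess trend (span 0.3) of its log2 deviation on log2 coding length, its combinations with the block and with the second 200 Gy library left out, the removal of ribosomal RNA genes, both scalings and left-out libraries for lists, and the DESeq2 Wald test for shared calls.

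The steps were tested on simulated counts of the 14417 genes with 200 changed genes. Without a length trend, the test recovered 0% of 2-fold, 29.9% of 4-fold and 78.8% of 8-fold changes for 200 Gy against 0 Gy, with 3 false calls. For 400 Gy against 0 Gy it recovered 1.49%, 40.3% and 84.8% with 5 false calls, and for 400 Gy against 200 Gy 0%, 23.9% and 78.8% with 6. With the length trend of the real libraries added, false calls were 295, 79 and 2336 in that order, and 6, 1 and 3 with the length correction. The added trend came from the same kind of loess fit that the correction removes. The counts with the correction were therefore bound to be low and do not test it on the real libraries.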

Results

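Gene expression was measured by RNA sequencing in young adult hermaphrodites of the nematode Caenorhabditis elegans that had received X-rays at 0, 200 or 400 Gy (gray, the unit of absorbed dose). Whole-worm total RNA gave 6 libraries, 2 at each dose. The libraries held 10270678 and 9930689 gene counts at 0 Gy, 9554479 and 11011227 at 200 Gy, and 12315765 and 10729139 at 400 Gy. Of 45292 genes listed, 14417 had enough counts to be tested. The labels do not say that the libraries of a dose came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Values per gene are CPM, the count relative to the library's total, after scaling by the trimmed mean of M-values (TMM), given as mean ± SD with n = 2 libraries per dose. Log2 fold changes are given ± their standard error (SE), and positions refer to the WBcel235 genome build. The lists of genes were fixed before the data were examined.

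The libraries differed in how counts were spread over short and long genes. Against 0 Gy, the fold changes at 200 Gy decreased with coding length (Spearman correlation across genes -0.53), while those at 400 Gy increased with it (0.39). Genes are not independent replicates, so no p-value is attached. In the tenth of genes with the longest coding sequences, the median log2 fold change was -1.33 at 200 Gy and 0.95 at 400 Gy. In the tenth with the shortest, it was 0.86 and -0.49. The slope of each library's deviation on log2 coding length was 0.069 and 0.052 at 0 Gy, -0.28 and -0.53 at 200 Gy, and 0.42 and 0.28 at 400 Gy. A fit that removed this trend from each library was added after the data were examined, and its values are given below as length-corrected. A ribosomal RNA gene, rrn-3.1, took from 0.694% to 9.24% of the counts of a library, with the higher share in replicate 2 at each dose.

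**Figure D1:**
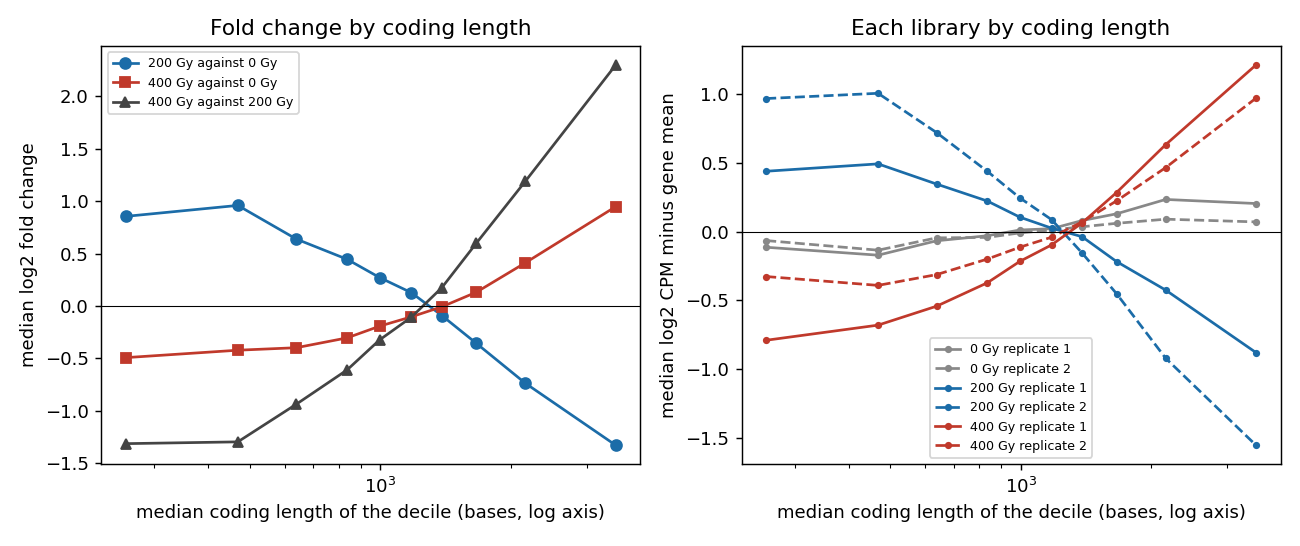
Median log2 fold change of each comparison (left) and median deviation of each library's log2 CPM from the gene's mean over libraries (right), in 10 groups of tested genes ordered by coding length (bases, log axis). The 400 Gy against 200 Gy line runs from -1.31 in the shortest genes to 2.3 in the longest.

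The comparison of 200 Gy with 0 Gy asked which transcripts differed after the lower dose. The largest rise was that of mul-1 (chromosome IV, 4121371 to 4123020), which encodes a mucin-like protein: it stood at 12.15 ± 1.67 CPM at 0 Gy and 774 ± 280.0 CPM at 200 Gy (log2 fold change 5.99 ± 0.47, adjusted p = 0.019). The glutathione S-transferase gene gst-38, of a family that conjugates glutathione to reactive compounds, went from 175 ± 64.4 to 1892 ± 941 CPM (3.44 ± 0.53, adjusted p = 0.0213). In its family, 14 of 41 tested members rose and 0 fell, or 20 adjusted over the list alone (median log2 fold change 1.45; camera adjusted p = 9.23e-09, and adjusted p = 0.708 with an estimated correlation). The study named this family from these samples, so its direction is not independent evidence. Further members were gst-5 (2.65 ± 0.36) and gst-20 (2.3 ± 0.35), and closely related members of such families can share reads. Among C-type lectins, sugar-binding proteins of which many respond to microbes, 23 of 132 tested members rose and 4 fell, led by clec-265 (3.40 ± 0.49) and clec-4 (3.30 ± 0.43). Among lysozymes and antimicrobial peptides 16 of 70 tested members rose and 0 fell, with lys-1 at 2.61 ± 0.40, lys-2 at 2.79 ± 0.40 and abf-5 at 3.93 ± 0.81. The 200 Gy libraries differed for abf-5, with 4.60 and 19.3 CPM. The camera adjusted p was 6.44e-06 for the lectins and 5.35e-08 for the lysozyme list, and adjusted p = 0.708 and adjusted p = 0.708 with an estimated correlation. With the length correction the 3 lists were called in the same direction (camera adjusted p = 1.98e-05, 3.00e-05 and 0.00601) with smaller medians, 0.89, 0.73 and 0.50. Fewer members then passed: 5 glutathione S-transferases rose, 9 lectins rose and 2 fell, and 3 of the lysozyme list rose and 2 fell. The next 3 lists, of detoxification and defence genes, were not called. Of 52 tested cytochrome P450 genes 2 rose and 3 fell (median -0.16, camera adjusted p = 0.262), and of 58 tested UDP-glucuronosyltransferase genes 2 rose and 3 fell (median 0.60, camera adjusted p = 0.087). The latter list was called higher with members of at least 5 CPM (camera adjusted p = 0.0359, 3.81e-05 to 0.878 over 14 alternatives) and length-corrected (camera adjusted p = 0.000211, and adjusted p = 0.836 with an estimated correlation). In the intracellular pathogen response list 0 of 39 rose and 1 fell in edgeR, with a median of -0.025 although camera's direction was up (camera adjusted p = 0.766).

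Other genes with large rises were Y41C4A.11 (chromosome III, 11719900 to 11723513; 7.63 ± 0.828 to 155 ± 12.18 CPM, log2 fold change 4.34 ± 0.38), the folate transporter gene folt-2 (3.58 ± 0.39), T22B7.3 (3.52 ± 0.57) and the collagen genes col-137 (3.60 ± 0.84), col-88 (3.48 ± 0.78) and col-96 (2.81 ± 0.38). The adjusted p-values of these 6 genes lay below the threshold of 0.05 in edgeR. Of 145 tested cuticle collagens, 29 rose and 7 fell (camera adjusted p = 0.0418, adjusted p = 0.832 with an estimated correlation, and 0.28 length-corrected). The major sperm proteins, small cytoskeletal proteins of sperm, had a median log2 fold change of 2.19: 6 of 26 tested members rose and 0 fell, among them msp-40 (3.06 ± 0.74) and msp-64 (2.95 ± 0.73). The 200 Gy libraries had medians of 0.93 and 2.75, the list's median was 0.81 without the second of them and 1.2 length-corrected, and 0 members passed length-corrected in edgeR. These genes are near-identical copies, so counts of single members are uncertain. Other sperm genes had a median of 1.1 with 0 of 31 past the threshold. The camera adjusted p was 1.27e-06 and 0.0284 for the sperm lists (adjusted p = 0.708 and adjusted p = 0.775 with an estimated correlation). The other sperm genes lost their call with members of at least 5 CPM (camera adjusted p = 0.175, 0.00131 to 0.775 over 14 alternatives), and their median was 0.22 without the second 200 Gy library. Proteasome subunits (median 0.94, 6 of 33 rose, among them pas-2 at 1.77 ± 0.36) and oxidative phosphorylation genes (median 0.91, 8 of 44 rose, among them cox-17 at 1.53 ± 0.31) were called higher (camera adjusted p = 4.43e-06 and 3.79e-08; adjusted p = 0.708 for both with an estimated correlation). Length-corrected, both lists were called (camera adjusted p = 1.98e-05 and 0.000114; medians 0.74 and 0.63), with 0 members of either past the threshold in edgeR. Ribosomal proteins and the Sm-like lsm proteins of RNA processing are short. Of these, 7 of 80 and 6 of 8 rose, the latter including lsm-6 (1.52 ± 0.30). Their camera adjusted p of 9.23e-09 and 0.000217 became 0.254 and 0.193 with the length correction, and adjusted p = 0.708 with an estimated correlation for both. The study named the lsm family too, so its direction is not independent evidence.

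Genes that fell at 200 Gy included many of the cuticle-forming epidermis and of early embryos. In the hypodermis list 16 of 30 members fell and 0 rose (median -1.73), among them noah-1 (66.2 ± 5.64 to 4.28 ± 0.061 CPM, -3.95 ± 0.51, adjusted p = 0.0208), the fibrillin-like fbn-1 (-4.12 ± 0.61) and the hedgehog-related qua-1 (-4.27 ± 0.71). Of the genes first transcribed in early embryos 8 of 25 fell and 0 rose (median -1.24), with vet-2 at -3.16 ± 0.39, vet-1 at -2.36 ± 0.46 and pes-10 at -2.85 ± 0.64. Both lists were called by camera (adjusted p = 8.27e-08 and 4.84e-05). They were also called with the length correction (camera adjusted p = 6.20e-05 and 1.15e-06, medians -1.31 and -1.22, 3 and 4 members falling). With an estimated correlation both had camera adjusted p = 0.708. For the early embryo list that estimate was 0.0108, close to the preset 0.01, so in this list the correlation did not make the change. Some other lists had higher estimates in this comparison, such as 0.10 for C-type lectins, 0.69 for DNA repair and 0.93 for major sperm proteins. For such lists the preset may make the camera p-values too small. In fry the early embryo list had adjusted p = 0.0389. Large falls outside these lists were those of clec-180 (-4.55 ± 0.73) and bus-1 (-4.39 ± 0.86). The 200 Gy libraries had 0.837 and 1.25 CPM of clec-180 and 0.697 and 0.578 of bus-1, so both falls rest on few reads.

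DNA repair genes were lower: 22 of 56 fell and 0 rose (median -0.99), among them rad-50, part of the complex that processes broken DNA ends (75.3 ± 6.15 to 10.3 ± 2.42 CPM, -2.87 ± 0.38, adjusted p = 0.0208), the polymerase theta gene polq-1 (-2.49 ± 0.36) and the helicase gene rtel-1 (-2.11 ± 0.33). In the damage checkpoint and apoptosis list 7 of 35 fell, among them atl-1, the ATR kinase (-2.62 ± 0.38). The checkpoint list had medians of 0.010 and -0.88 in the 200 Gy libraries. Many of these genes are long: the repair list had a median coding length of 2252 bases. With the length correction the median of the repair list was -0.45, with 1 member past the threshold (camera adjusted p = 3.76e-08 before and 0.000801 after; adjusted p = 0.708 with an estimated correlation). Its medians in the 200 Gy libraries were -0.42 and -1.44. The checkpoint list lost its call (0.018 before and 0.252 after; adjusted p = 0.775 with an estimated correlation). Neuronal genes (14 of 36 fell and 1 rose), with the calcium channel gene unc-2 at -4.04 ± 0.48 and unc-13 at -3.38 ± 0.53, had camera adjusted p = 4.89e-05 before and 0.00211 after the correction, which left 2 falling (adjusted p = 0.708 with an estimated correlation). Genes of RNA interference (12 of 36 fell and 1 rose), with the Dicer gene dcr-1 at -2.49 ± 0.36 and rrf-1 at -2.46 ± 0.36, went from 4.53e-05 to 0.84 (adjusted p = 0.708 with an estimated correlation). Oocyte and germline genes had a median of -0.059 (2 of 69 fell; camera adjusted p = 0.0755), which joins libraries with medians of 0.75 and -1.40 and turned with single libraries left out, from -1.68 to 0.62. In this list 65 of the 69 members were higher in replicate 1 than in replicate 2 at all 3 doses.

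Of the other families that the study named, whose directions are not independent evidence, guanylate cyclases (gcy) were lower. In this family 4 of 14 fell, gcy-32 among them (-4.07 ± 0.82). The 200 Gy libraries had 0.139 and 0.289 CPM of gcy-32, so its fold change rests on few reads. Camera gave adjusted p = 0.00125 for the family, adjusted p = 0.708 with an estimated correlation and 0.618 length-corrected. Diacylglycerol kinases had a median of -1.42 (1 of 4 fell; camera adjusted p = 0.0738), and Skp1-related genes a median of 0.17 (1 of 19 rose; camera adjusted p = 0.601). Of the signalling genes the study named, plc-3, a phospholipase C (-1.49 ± 0.36, adjusted p = 0.0346), and lin-45, the Raf kinase (-1.84 ± 0.52, adjusted p = 0.0485), fell. The values of cbp-1 (-1.70 ± 0.63, adjusted p = 0.092) and the phosphoinositide kinase gene age-1 (-1.02 ± 0.68, adjusted p = 0.307) did not pass. Length-corrected, the log2 fold changes of plc-3 and lin-45 were -0.093 and -0.93, with adjusted p = 0.896 and 0.16, where 17 alternatives gave 0.0054 to 0.896 and 0.00122 to 0.413. Of the genes known for the response to DNA damage in the germline, the cell death gene egl-1 stood at 0.858 ± 0.639 and 3.65 ± 1.35 CPM (2.06 ± 0.68, adjusted p = 0.0706), cep-1, the worm p53, had -0.90 ± 0.32, adjusted p = 0.0806, and the recombinase gene rad-51 had -0.070 ± 0.36, adjusted p = 0.906. The counts of ced-13 were too low to test: 1 and 1 at 0 Gy, 7 and 7 at 200 Gy, and 5 and 2 at 400 Gy. The yolk gene vit-2 had -0.32 ± 0.64, adjusted p = 0.745.

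In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2269 of 14417 genes passed the threshold of 0.05 at 200 Gy, 1013 higher and 1256 lower. The libraries of the 2 doses did not overlap for 63.2% of genes, where chance gives 33.3% for each gene. Genes move together, as with the length trend, and separate handling of the doses could raise this share too. The share is therefore no test of an effect of dose. The length-corrected fit called 426 genes (216 higher, 210 lower), 353 of them shared with the first fit in the same direction. Of the genes named above, these also did not pass in it, with log2 fold changes of 2.05 for msp-40, 1.94 for msp-64, 1.28 for pas-2, 0.79 for cox-17, 0.72 for lsm-6, -2.05 for fbn-1, -2.96 for qua-1, -0.91 for polq-1, -0.96 for rtel-1, -0.72 for atl-1, -2.22 for unc-2, -1.46 for unc-13, -0.80 for dcr-1, -0.85 for rrf-1 and -3.36 for gcy-32. The count moved with single libraries: it was 0 without either library at 0 Gy (3155 and 2975 genes at an unadjusted p under 0.05), 4644 and 1455 without the first or second at 200 Gy, and 1265 and 1492 without the first or second at 400 Gy. In edgeR 0 genes passed 0.01, where 5358 had an unadjusted p under 0.05 and the DESeq2 Wald test called 3327 at 0.05, and without ribosomal RNA rows the split was 708 higher and 1459 lower, and with upper-quartile scaling it turned to 1096 and 1059.

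**Figure D2:**
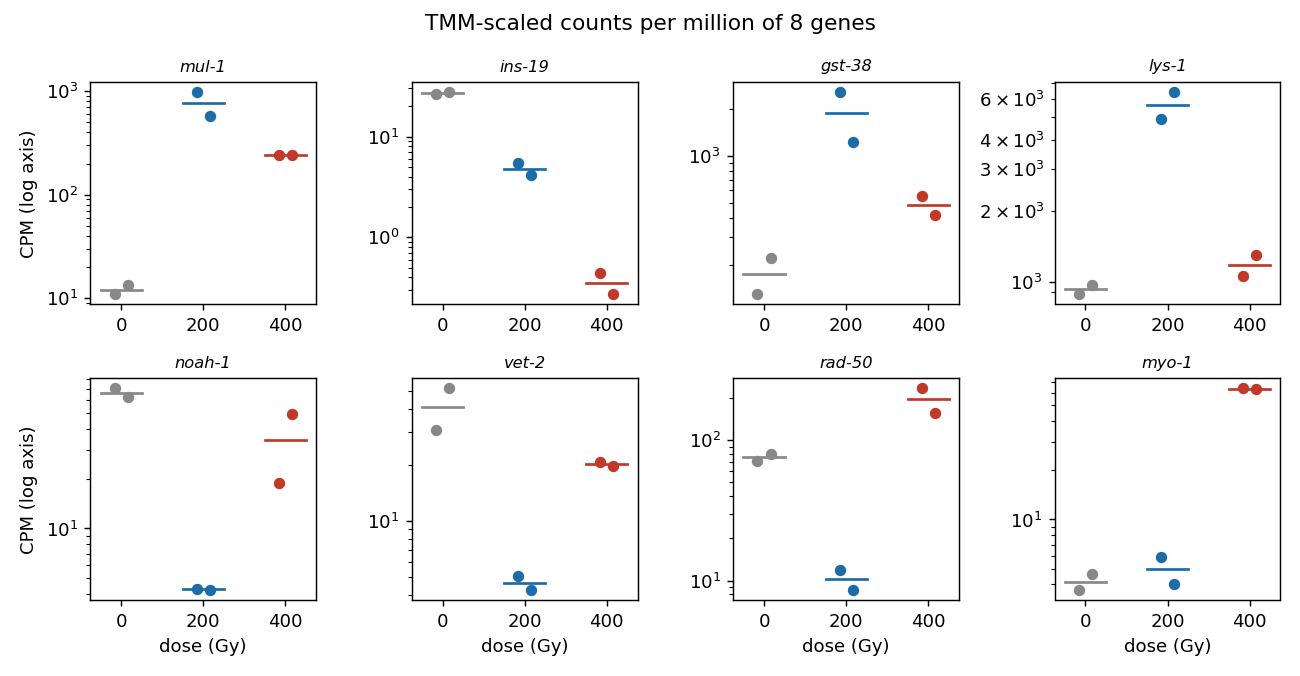
TMM-scaled CPM (log axis) of 8 genes by dose in Gy; points are the 2 libraries of a dose and bars their mean. The mean of mul-1 was 12.15 CPM at 0 Gy, 774 at 200 Gy and 240.3 at 400 Gy, and that of ins-19 was 26.8, 4.79 and 0.355.

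At 400 Gy against 0 Gy the number of calls depended on the libraries in the fit. With only the 4 libraries compared, 2191 genes passed in edgeR, against 1652 for 200 Gy against 0 Gy. With all 6 libraries in 1 fit, 7 genes passed the threshold at 400 Gy, a count that does not measure a weaker response than at 200 Gy. Rises were those of mul-1 (240.3 ± 0.164 CPM at 400 Gy; log2 fold change 4.30 ± 0.44, adjusted p = 0.0324), the pharyngeal muscle myosins myo-1 (4.16 ± 0.672 to 63.3 ± 0.349 CPM, 3.92 ± 0.37, adjusted p = 0.0324) and myo-2 (3.26 ± 0.34, adjusted p = 0.0344), the matrix proteins him-4, a hemicentin (4.30 ± 0.42, adjusted p = 0.0324), and epi-1, a laminin chain (3.19 ± 0.36, adjusted p = 0.0447), and Y113G7C.1 (4.30 ± 0.49, adjusted p = 0.047). The insulin-like peptide gene ins-19 (chromosome II, 3126075 to 3126441) fell from 26.8 ± 0.848 to 0.355 ± 0.117 CPM (-6.19 ± 0.50, adjusted p = 0.0218). Next by p-value among lower genes, and not past the threshold, came ilys-5, an invertebrate lysozyme (-3.84 ± 0.48, adjusted p = 0.0504), F15A4.10 (-2.43 ± 0.32, adjusted p = 0.0504), C02F12.5 (-2.61 ± 0.36, adjusted p = 0.0512) and Y22D7AR.10 (-2.31 ± 0.32, adjusted p = 0.0512).

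By list, genes of the pharynx, the feeding organ, had the highest median at 400 Gy in the fit without the length correction (2.25). Of the 13 pharynx genes 2 rose, or 10 adjusted over the list alone. Body wall muscle genes had a median of 0.71 (0 of 38 rose, 14 adjusted over the list alone). Major sperm proteins (2.00) and other sperm genes (2.08) also had high medians, with 0 members past the threshold over all genes and 20 of 26 and 13 of 31 adjusted over the list alone. The camera adjusted p was 7.25e-09, 7.25e-09, 2.68e-09 and 2.11e-08 in that order, and 4.40e-10, 0.000105, 1.02e-20 and 2.94e-10 length-corrected. With an estimated correlation these were adjusted p = 0.597, adjusted p = 0.76, adjusted p = 0.977 and adjusted p = 0.76. Early embryo genes (-0.92; camera adjusted p = 8.28e-05, 6.38e-05 length-corrected) and hypodermis genes (-0.69; 0.0172, 5.17e-08 length-corrected) were lower as lists, with 0 single members past the threshold in either (adjusted p = 0.597 and adjusted p = 0.988 with an estimated correlation). The hypodermis list lost its call with members of at least 5 CPM (camera adjusted p = 0.0526, 5.17e-08 to 0.988 over 14 alternatives), and the 400 Gy libraries had medians of -1.35 and -0.39.

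DNA repair and RNA interference genes, lower as lists at 200 Gy, were higher as lists at 400 Gy, with medians of 0.40 and 0.69. The 400 Gy libraries stood at 0.66 and 0.18 for DNA repair and at 0.95 and 0.49 for RNA interference. Camera gave adjusted p = 0.00198 and 9.19e-05, and adjusted p = 0.988 for both with an estimated correlation. Length-corrected neither was called (camera adjusted p = 0.638 and 0.919). Oocyte and germline genes had a median of 0.66 (camera adjusted p = 0.00112, 0.0301 length-corrected, adjusted p = 0.988 with an estimated correlation). The medians of the libraries overlapped between the doses for this list, with 0.56 and -0.56 at 0 Gy and 1.21 and 0.36 at 400 Gy. Lysozymes and antimicrobial peptides had a median of -0.65, with -1.09 and -0.28 in the 400 Gy libraries (camera adjusted p = 0.000257, 0.169 length-corrected, adjusted p = 0.988 with an estimated correlation). Of the families named by the study, again no independent evidence, lsm (-0.97; camera adjusted p = 0.000454, 0.103 length-corrected) and skr (-0.89; 4.69e-06, 0.00165 length-corrected) were lower as lists (adjusted p = 0.76 for both with an estimated correlation). The gst (-0.19; camera adjusted p = 0.382), gcy (0.56; 0.56) and dgk (0.32; 0.648) families were not called. The signalling genes were called as a list (median 1.21; camera adjusted p = 0.0172, 0.448 length-corrected; adjusted p = 0.977 with an estimated correlation), with none past the threshold singly: plc-3 had 1.36 ± 0.34, adjusted p = 0.102, cbp-1 2.06 ± 0.63, adjusted p = 0.128, lin-45 1.07 ± 0.50, adjusted p = 0.244 and age-1 0.99 ± 0.68, adjusted p = 0.41. For egl-1 the value was 1.65 ± 0.68, adjusted p = 0.203, for cep-1 -0.46 ± 0.31, adjusted p = 0.406, for rad-51 0.11 ± 0.36, adjusted p = 0.881 and for vit-2 0.77 ± 0.64, adjusted p = 0.499.

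The 7 calls at 400 Gy, 6 higher and 1 lower, came from edgeR, and 3244 genes had an unadjusted p under 0.05. DESeq2 size factors gave 273 calls (194 higher, 79 lower), upper-quartile scaling 10 (7 higher, 3 lower) and the DESeq2 Wald test 1353. The length-corrected fit called 2 of the 7, mul-1 and ins-19. The other 5 had smaller fold changes in it, 3.18 ± 0.56 for Y113G7C.1, 2.48 ± 0.35 for myo-1, 1.80 ± 0.37 for myo-2, 1.80 ± 0.47 for him-4 and 1.06 ± 0.39 for epi-1, and all 7 were called in the same direction with the correction and no second 200 Gy library. Y113G7C.1 also lost its call with upper-quartile scaling and among genes of at least 5 CPM. The libraries of these doses did not overlap for 59.2% of genes, where chance gives 33.3% for each gene, again no test of dose. Leaving out one library gave 0 calls without either library at 0 Gy (1750 and 1357 genes at an unadjusted p under 0.05) or either at 400 Gy (2028 and 2258), and 2273 and 2295 without the first or second at 200 Gy. In data simulated without a trend, the test recovered 40.3% of genes changed 4-fold and 84.8% of genes changed 8-fold in this comparison. With the length trend added, the same fit recovered 38.8% and 71.2%. In the real libraries unc-22, with 12.4 and 36.2 CPM at 0 Gy and 621 and 592 at 400 Gy, was not called. The simulated shares are therefore no measure of how many real changes were found.

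**Figure D3:**
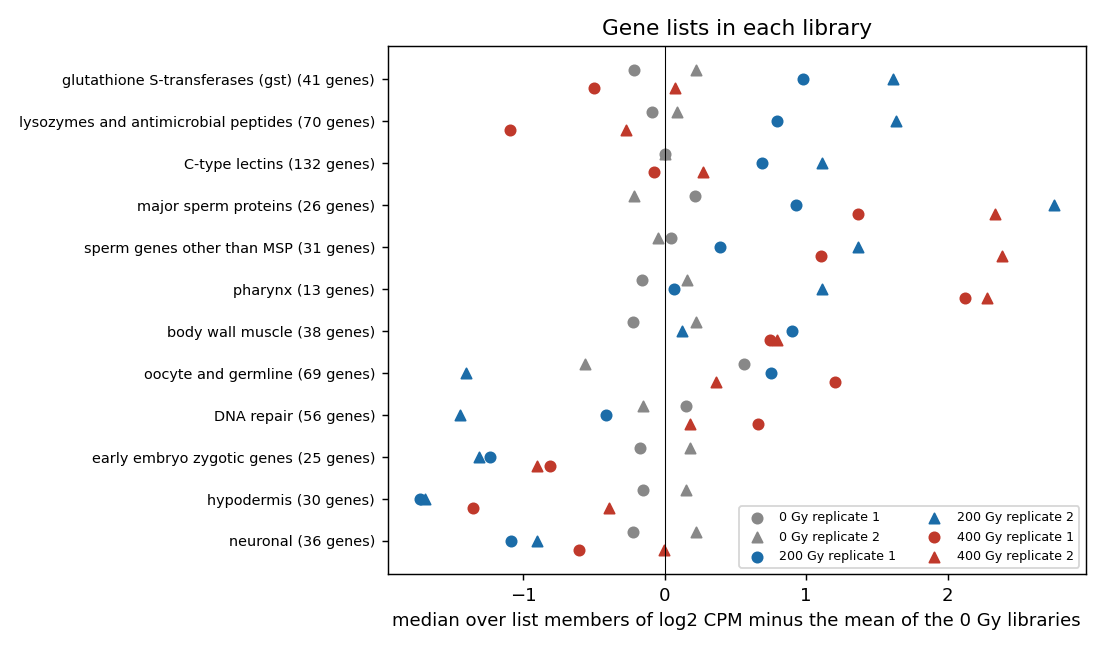
Median over the members of 12 gene lists of log2 CPM minus the mean of the 0 Gy libraries, in each of the 6 libraries. Early embryo genes lie at -1.23 and -1.31 in the 200 Gy libraries and at -0.81 and -0.90 in the 400 Gy libraries.

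The irradiated groups were also compared with each other. The gene unc-22, which encodes twitchin, stood at 4.12 ± 2.08 CPM at 200 Gy and 607 ± 20.6 CPM at 400 Gy (log2 fold change 7.18 ± 0.72, adjusted p = 0.00265), and ttn-1, the titin gene (6.45 ± 0.61), dig-1 (5.61 ± 0.54), ketn-1 (5.59 ± 0.62) and the ryanodine receptor gene unc-68 (5.35 ± 0.49) also rose. Their coding lengths ran up to 55975 bases. Length-corrected, unc-22 had 1.78 (adjusted p = 0.0872, the highest of 17 alternatives, the lowest being 1.22e-33), ttn-1 and dig-1 turned to -0.31 and -0.62, and ketn-1 and unc-68 had 0.86 ± 0.44 and 0.45 ± 0.42, none of them past the threshold. In the body wall muscle list 13 of 38 rose and 4 fell, and the list was not called (median 0.12, camera adjusted p = 0.0533; length-corrected -0.20, adjusted p = 0.368). Pharynx genes rose in 7 of 13 cases (camera adjusted p = 0.00455, 0.0192 length-corrected, adjusted p = 0.696 with an estimated correlation), or 2 length-corrected, although myo-1 (3.68 ± 0.36) and myo-2 (2.36 ± 0.33) had 0.54 and -0.85 length-corrected. DNA repair genes were higher, with 27 of 56 rising and 0 falling (median 1.49), rad-50 (4.25 ± 0.40) and polq-1 (3.82 ± 0.37) among them, and the list was also called length-corrected, with a median of 0.47 and 3 members rising (camera adjusted p = 3.35e-09 and 0.000332; adjusted p = 0.745 with an estimated correlation). RNA interference genes rose in 17 of 36 cases and fell in 1, with dcr-1 (3.84 ± 0.39) and rrf-1 (3.05 ± 0.37), and were not called length-corrected (camera adjusted p = 6.24e-08 and 0.826; adjusted p = 0.745 with an estimated correlation). The hypodermis list, with 12 of 30 rising and 2 falling, went from 0.017 to 0.558 (adjusted p = 0.745 with an estimated correlation).

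Members of 5 lists were lower at 400 Gy than at 200 Gy. Lysozymes and antimicrobial peptides fell in 41 of 70 cases and rose in 0 (median -1.90), with the caenacin gene cnc-2 at -4.26 ± 0.62 and lys-5 at -3.44 ± 0.41. Glutathione S-transferases fell in 19 of 41 cases (median -1.75; gst-5 -2.51 ± 0.35), C-type lectins in 30 of 132 with 5 rising, oxidative phosphorylation genes in 17 of 44 (cox-17 -2.89 ± 0.33) and proteasome subunits in 9 of 33. These 5 lists were called by camera in both fits, with adjusted p = 1.94e-11, 8.09e-09, 0.00116, 6.16e-06 and 0.000404, and length-corrected 4.17e-05, 0.00011, 0.00267, 0.013 and 0.000974. With an estimated correlation they had adjusted p = 0.739, adjusted p = 0.696, adjusted p = 0.745, adjusted p = 0.696 and adjusted p = 0.745. Length-corrected, their medians were -0.76, -0.87, -0.61, -0.29 and -0.61 (before -1.90, -1.75, -0.83, -0.87 and -0.83), and 7, 1, 6, 4 and 0 members fell. Cytochrome P450 genes (1 of 52 rose and 0 fell) and UDP-glucuronosyltransferases (2 of 58 rose and 2 fell) were not called (camera adjusted p = 0.796 and 0.336), but were called lower length-corrected (camera adjusted p = 0.0314 and 0.00011; adjusted p = 0.959 for both with an estimated correlation). Ribosomal protein genes fell in 34 of 80 cases, rps-17 (-2.44 ± 0.37) and rps-28 (-2.05 ± 0.33) among them, and were not called length-corrected (camera adjusted p = 4.38e-09 and 0.744; adjusted p = 0.745 with an estimated correlation). Single genes with large falls were C36C9.10 (170.1 ± 25.4 to 8.61 ± 3.87 CPM, -4.30 ± 0.45, adjusted p = 0.00265), F39D8.7 (-4.2 ± 0.58) and ins-19 (-3.70 ± 0.49).

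Among the families that the study named from these samples, lsm genes fell in 7 of 8 cases (lsm-6 -2.60 ± 0.31; camera adjusted p = 2.17e-05, 0.00955 length-corrected) and skr genes in 10 of 19 (7.30e-05, 0.607 length-corrected), while gcy genes rose in 6 of 14 (0.00131, 0.548 length-corrected) and dgk genes in 3 of 4 (0.119). With an estimated correlation the first 3 had adjusted p = 0.696. These counts are not independent evidence of direction. The signalling list rose in 3 of 4 cases (camera adjusted p = 0.0033, 0.146 length-corrected, adjusted p = 0.696 with an estimated correlation): plc-3 (2.85 ± 0.37, adjusted p = 0.0033), cbp-1 (3.76 ± 0.68, adjusted p = 0.00689) and lin-45 (2.91 ± 0.54, adjusted p = 0.00726) passed and age-1 did not (2.00 ± 0.70, adjusted p = 0.0612). Length-corrected, plc-3, cbp-1 and lin-45 had 0.40 ± 0.37, 0.72 ± 0.44 and 1.42 ± 0.39 and did not pass. Neither egl-1 (-0.42 ± 0.63, adjusted p = 0.642), cep-1 (0.44 ± 0.31, adjusted p = 0.312), rad-51 (0.18 ± 0.36, adjusted p = 0.728) nor vit-2 (1.09 ± 0.65, adjusted p = 0.23) passed. In edgeR 4495 genes were called, 2157 higher and 2338 lower at 400 Gy, and the length-corrected fit called 646 (298 higher, 348 lower), 506 of them shared in direction. Other genes named for this comparison that did not pass in it had log2 fold changes of 0.93 for polq-1, 0.69 for dcr-1, 0.12 for rrf-1, -1.16 for rps-17, -0.83 for rps-28, -2.44 for ins-19 and -1.31 for lsm-6. The libraries of the 2 doses did not overlap for 65.7% of genes, where chance gives 33.3% for each gene, again no test of dose. Without the first library at 400 Gy the count was 1319 and without the second 2409. The balance turned with DESeq2 size factors (2420 higher, 2124 lower) and without ribosomal RNA genes (2460 higher, 1927 lower).

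The test for any effect of dose called 4336 of 14417 genes in edgeR, and 994 length-corrected, 847 of them shared. It called 1273 and 1113 genes without the first or second library at 0 Gy, 1381 and 2257 without the first or second at 400 Gy, and 6593 without the first at 200 Gy.

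The responses to the 2 doses were compared with each other. Of the genes called against 0 Gy, mul-1 was higher and ins-19 lower at both doses. Independent lists of these sizes would share 0.422 higher and 0.0871 lower genes, and 20 simulations of unchanged groups against the same controls shared 0 in edgeR. The simulated groups gave 0 calls at 200 Gy, so they could share none and this 0 is no yardstick for the 2 genes. Without single libraries the number of shared calls ran from 0, without either library at 0 Gy or either at 400 Gy, to 551 without the first and 200 without the second at 200 Gy. Across genes, the fold changes had a Pearson correlation of 0.22, against 0.49 ± 0.0099 (SD, 20 simulations) for unchanged groups, since both comparisons share the 0 Gy libraries. Their covariance was 0.31 against 0.17 simulated, a difference of 0.14. The share of genes with the same sign at both doses was 48.05%, and 62.0% length-corrected, against 66.4% ± 0.40 (SD) simulated. Both fits were set against the same simulations. In unchanged groups the shared controls alone make the share and the correlation high. Changes at only 1 dose would lower both, so a value below the simulated one does not measure disagreement of the doses. Length-corrected, the correlation was 0.51 and the covariance 0.56, a difference of 0.39 from the simulated value. The 2 libraries at 0 Gy were not split, 1 to each dose, so part of the excess in covariance may come from the shared controls.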

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

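The length correction, its combinations, the removal of ribosomal RNA genes, the scalings and left-out libraries for lists, and the DESeq2 Wald test for shared calls were chosen after the data were examined. With DESeq2 size factors 89 of 94 named gene values kept their direction and their side of the threshold, with upper-quartile scaling 89, with the DESeq2 Wald test 85, without a count filter 90, with only the 4 libraries compared 87, and without ribosomal RNA genes 94. Upper-quartile scaling moved the median of all genes to 0.19 for 200 Gy against 0 Gy and -0.29 for 400 Gy against 200 Gy, from 0.099 and -0.10. Members of at least 5 CPM ended the calls of the sperm genes other than MSP at 200 Gy and of the hypodermis at 400 Gy. Upper-quartile scaling ended the calls of plc-3 and of the sperm genes other than MSP at 200 Gy and of Y113G7C.1 at 400 Gy. With the length correction 48 of 94 values kept direction and side, 36 were no longer past the threshold and 10 turned. For the lists described, the estimated correlation gave the highest adjusted p of their alternatives, except in 12 of the list results (RNA interference, Skp1-related, diacylglycerol kinase, oocyte, ribosomal, cytochrome P450, UDP-glucuronosyltransferase, intracellular pathogen response and, at 400 Gy, glutathione S-transferase lists), whose highest was 0.997. Without either 0 Gy library, 47 values were no longer past the threshold, where a lone library was assumed to vary like the other doses and 1 fewer library was fitted. Except where stated, the cause was not tested.

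For 200 Gy against 0 Gy the count of 2269 became 426 with the length correction, 750 with that and no second 200 Gy library, and 0 in edgeR at 0.01 (5358 genes at an unadjusted p under 0.05, 3327 by the DESeq2 Wald test at 0.05). For 400 Gy against 0 Gy the count of 7 became 273 with DESeq2 size factors, 1353 with the DESeq2 Wald test, 230 without the count filter, 2191 with only the 4 libraries compared, 2 with the length correction, 1533 with that and no second 200 Gy library, and 0 in edgeR at 0.01 (3244 genes at an unadjusted p under 0.05). For 400 Gy against 200 Gy the count of 4495 became 646, 886 and 1773, and for any dose 4336 became 994, 2441 and 621, with the length correction, with that and no second 200 Gy library, and at 0.01. The 2 genes shared by both doses became 0 in edgeR at 0.01 and 340 with the DESeq2 Wald test. Leaving out 1 library gave 0 to 4644 calls, 0 to 2295, 1319 to 5781 and 1113 to 6593 in that order, and 0 to 551 shared genes. Of 46 lists, 25, 18 and 27 were called, against 0, 0 and 0 with camera's estimated correlation and 2, 0 and 7 with fry, which asks another question. With the length correction 21, 10 and 18 were called, of which 14, 8 and 10 had been called in the same direction without it, and 11 at 400 Gy with the replicate block as well. Left-out libraries gave 22 to 33, 12 to 25 and 23 to 28.

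With the replicate block the counts were 6444, 3586, 7640 and 8949, with 928 shared genes, and with the length correction as well 4598, 2426, 4522 and 6505, with 979. Replicate numbers are shared by the doses in the labels and nothing says that they pair cultures. The difference between replicates correlated across genes at 0.48 between 0 and 200 Gy, 0.37 between 0 and 400 Gy and 0.60 between 200 and 400 Gy, a hint from the data and not from the design. The block ended no call among the named genes and lists, and 14 gene values and 2 lists came past the threshold. The lists were oocyte and germline (adjusted p = 0.0189 against 0.0755 without the block, 2.16e-09 to 0.919 over 14 alternatives) and UDP-glucuronosyltransferases (0.0372 against 0.087, 3.81e-05 to 0.878 over 14 alternatives), both for 200 Gy against 0 Gy. With the length correction as well, the 7 genes called for 400 Gy against 0 Gy stayed called.

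Directions turned as follows, lists by camera's direction with their median log2 fold change. With the length correction these were oocyte and germline 0.16, Skp1-related proteins -0.52, intracellular pathogen response -0.18, age-1 0.12 and vit-2 1.07 for 200 Gy against 0 Gy, glutathione S-transferases 0.15, guanylate cyclases -0.50, diacylglycerol kinases -0.36 and vit-2 -0.53 for 400 Gy against 0 Gy, and guanylate cyclases -0.016, diacylglycerol kinases 0.10, hypodermis -0.00010, body wall muscle -0.20, ttn-1 -0.31, dig-1 -0.62, myo-2 -0.85, age-1 -0.043, egl-1 0.86, cep-1 -0.51 and vit-2 -1.60 for 400 Gy against 200 Gy. With that and the replicate block they were oocyte and germline -0.0017, Skp1-related proteins -0.54, intracellular pathogen response -0.12, age-1 0.047 and vit-2 1.03 for 200 Gy against 0 Gy, glutathione S-transferases 0.18, guanylate cyclases -0.49, diacylglycerol kinases -0.33 and vit-2 -0.55 for 400 Gy against 0 Gy, and guanylate cyclases 0.018, diacylglycerol kinases 0.12, hypodermis -0.023, body wall muscle -0.20, ttn-1 -0.28, dig-1 -0.58, myo-2 -0.81, egl-1 0.91, cep-1 -0.50 and vit-2 -1.59 for 400 Gy against 200 Gy. With the correction and no second 200 Gy library they were age-1 0.69, cbp-1 0.35, rad-51 0.20 and vit-2 1.46 for 200 Gy against 0 Gy, vit-2 -0.52 for 400 Gy against 0 Gy, and myo-2 -0.46, age-1 -0.61, egl-1 0.29, cep-1 -0.26, rad-51 -0.016 and vit-2 -1.97 for 400 Gy against 200 Gy. With upper-quartile scaling it was rad-51 0.013 for 200 Gy against 0 Gy.

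Left-out libraries turned some values, with ranges of -1.68 to 0.62 for oocyte and germline at 200 Gy against 0 Gy, -0.78 to 0.076 for cytochrome P450 at 200 Gy against 0 Gy, -0.49 to 0.70 for intracellular pathogen response at 200 Gy against 0 Gy, -0.53 to 0.17 for rad-51 at 200 Gy against 0 Gy, -1.55 to 0.22 for vit-2 at 200 Gy against 0 Gy, -0.14 to 0.35 for rad-51 at 400 Gy against 0 Gy, -0.13 to 0.44 for cytochrome P450 at 400 Gy against 200 Gy, -0.50 to 0.19 for UDP-glucuronosyltransferases at 400 Gy against 200 Gy, -0.67 to 0.19 for egl-1 at 400 Gy against 200 Gy, -0.072 to 0.66 for rad-51 at 400 Gy against 200 Gy. With members of at least 5 CPM, cytochrome P450 turned to 0.22 at 200 Gy against 0 Gy.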

Other observations

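The families below and every test here were chosen after the data were examined, except the tests of length bias, of tissue mix and of embryos, which were set before their results were seen. All 129 families of genes that share a name prefix and have enough members were tested with camera, and 38, 30 and 40 were called in the 3 comparisons, 0 with an estimated correlation. Touch receptor genes (mec, 15 tested) had a median log2 fold change of -1.56 at 200 Gy, where 7 fell, and -1.51 at 400 Gy, where 0 passed the threshold in edgeR (camera adjusted p = 0.000145 and 8.35e-05, and 0.000174 and 1.27e-06 length-corrected). With an estimated correlation they had adjusted p = 0.775 and adjusted p = 0.799. T-box transcription factors (tbx, 11 tested) had medians of -1.84 and -2.05, and F-box genes of the fbxb group (37 tested) -1.05 and -1.3. Their camera adjusted p was 0.00738 and 0.00338 for tbx, and 0.00469 and 7.67e-06 for fbxb, with adjusted p = 0.775 and adjusted p = 0.799 for both with an estimated correlation.

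Between the irradiated groups, mitochondrial ribosomal protein genes of the mrpl family were lower at 400 Gy, with 27 of 39 falling (median -1.32; camera adjusted p = 1.67e-08, 0.00202 length-corrected, median -0.58), and so were short-chain dehydrogenases (dhs), with 12 of 30 falling (median -1.34; 9.06e-05, 0.000376 length-corrected). The mrps genes, also of mitochondrial ribosomes, fell in 12 of 24 cases with 1 rising (median -1.09; 0.00136), and lost their call length-corrected (median -0.31, 0.37). With an estimated correlation all 3 families had adjusted p = 0.668. At 200 Gy dpy genes, which shape the body and cuticle, were lower, with 10 of 25 falling (median -1.47; camera adjusted p = 5.67e-05, 0.000174 length-corrected; adjusted p = 0.775 with an estimated correlation).

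The fold changes followed coding length in opposite directions at the 2 doses. If this came from a shift in the mix of tissues, the slope should shrink within tissue lists. Yet within 7 lists it was 131% ± 10.2 (SE), 203% ± 17.1 and 157% ± 6.02 of the slope over all genes. The lowest less 2 SE was 110.7%. These SE take the 249 genes as independent, which they are not, so they do not measure the spread between libraries. Transcription blocked along damaged genes predicts lower long genes at both doses, against a Spearman correlation of 0.3866 at 400 Gy. This test used coding length, which leaves out introns. With the genomic span of genes the correlation was -0.46 at 200 Gy and 0.28 at 400 Gy. Given coding length, the partial correlation with span was -0.041 and -0.072. Blocking alone would thus not give the trend at 400 Gy, but a block beneath another trend is not excluded. A length bias of the RNA or libraries may account for the trend, as the slope kept within lists (at least 131.2%) goes with it. The prediction set no upper limit. A bias alike for all genes would keep the slope and not steepen it, so the steeper slopes within lists stay unexplained. Any other cause that acts within tissues would keep the slope too. Both libraries of each irradiated dose had slopes of the same sign, so a bias from the dose and one from separate handling of the doses, for which the labels give no batch, cannot be told apart.

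Early embryo genes had lower medians at both doses, and the length correction, which would remove this if the length trend made it, kept at least 96.36% of the median. Less germline RNA would lower the oocyte and germline list too, whose lower median was -0.05855, with an SE between libraries taken as unpaired of 1.22 at 200 Gy and 0.70 at 400 Gy. By replicate number, which the labels do not pair, the list differed from 0 Gy by 0.19 and -0.84 at 200 Gy and by 0.64 and 0.93 at 400 Gy, so this stays open. Fewer or earlier-arrested embryos in the worms might account for it, as a hypothesis: of 30 further embryonic transcription factor genes 19 were tested, with length-corrected medians of -1.35 at 200 Gy and -0.6175 at 400 Gy, and 16 and 12 of the 19 lower before the correction. Limma's camera gave adjusted p = 1.23e-05 and 0.213 over the 3 comparisons, and adjusted p = 0.0732 and adjusted p = 0.374 with an estimated correlation, so both stay open.

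Germline genes were higher in replicate 1 than in replicate 2, with median log2 differences of 1.13, 1.76 and 0.78 at 0, 200 and 400 Gy, and 65 of 69 genes higher at all 3. The length correction kept at least 89.66% of the difference, against the length trend as its cause. The share of ribosomal RNA was higher in replicate 2 and stays open: the list stood at least 0.8322 above all genes, but scaling had already centred all genes, so this restates the pattern. A difference between the replicates in the worms' age, or in how they were grown or prepared, may remain but was not tested, and the design gives no biological explanation to test.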
